A study of Schizosaccharomyces pombe with 64 samples.

How the data were processed

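The series holds 64 one-colour arrays of fission yeast (Schizosaccharomyces pombe) RNA. Wild type and gcn2D cells, which lack the eIF2 alpha kinase Gcn2, were grown at 30 °C to an A600 of 0.3 to 0.5. Per the labels, untreated cells grew in complete minimal medium. Treated cells grew in that medium without histidine, and 10 mM 3-aminotriazole (3AT), an inhibitor of histidine synthesis, was added for 30 min, so the comparison of treated with untreated cells includes the difference in medium. Lysates of cycloheximide-treated cells were spun at 41000 rpm for 2 h through a 10 to 45% sucrose gradient, and 7 fractions were collected. Each culture gave 8 arrays, 1 per fraction and 1 of total RNA. There were 3 untreated and 3 treated wild type cultures, and 1 untreated and 1 treated gcn2D culture. The labels call the wild type cultures replicates and do not say that they were grown from separate starters or on separate days. They do not say which fraction number is the top of the gradient, and fractions are named here by number only.

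Per the labels, 200 ng of RNA was labelled with Cy3 for each array and hybridized to a custom Agilent array with 62976 spots. The scans were read with Agilent Feature Extraction 10.7.3.1, as the submitters' processing notes give it. Per the file headers, the processed signal of each spot is a background-subtracted and detrended intensity on a linear scale, with a flag for spots well above background. The table of the series, deposited by the authors, holds 1 intensity per probe and array. A check against the spot files showed that it is the median over a probe's spots times 1 factor per array, which brings the 75th percentile of every column close to a common value (2500 to 2509 for total RNA, 2482 to 2526 for fractions). Its column medians ran from 827.6 to 888.9 for total RNA and from 552.9 to 1117 for fractions. Its scale is linear, its columns are not centred and its values are levels with no sign, so neither scale, centring nor direction stayed unknown. The authors marked 40 probes as corrected for a paralog and left 25 without a value.

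The processed spot signals were used here. The log2 signal of a probe was the mean of the log2 values of its 6 to 10 spots, with spots flagged as outliers left out. Of 6711 non-control probes, 104 that the design marks as cross-hybridizing were left out, and 6607 were tested as genes, each with 1 probe. Names came from the array files and from the reference table, which matched 6424 probes. Genes whose probe shares sequence with another gene (191) were counted but not named. Coordinates are those in the array files, on the NCBI build that the array design names. No genome sequence was used, so leaders and upstream open reading frames were not analysed here.

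Total RNA arrays were scaled to the 75th percentile over all gene probes. Fraction arrays differ in how many probes stand above background, and a percentile over all probes follows that number. They were therefore scaled to the 75th percentile over the 748 probes well above background on all 56 fraction arrays, a choice made once the share of probes above background on each array had been seen and before any polysome index was tested. It departs from the design written before the data were examined, which had named each array's own percentile over all probes. That percentile is kept as an alternative. The polysome index of a gene in a culture is the mean log2 level in fractions 5 to 7 minus the mean in fractions 1 to 3. Per the labels equal amounts of RNA were labelled, so the index places a gene relative to the other genes of its gradient and is not a share of its molecules. The spike-in log2 signal ran from 11.85 to 17.27 on fraction arrays and from 9.789 to 10.91 on total RNA arrays, so equal input was not shown. Genes were kept for total RNA if well above background on at least 3 of 8 arrays (5087 genes) and for the index on at least 28 of 56 fraction arrays (3543 genes).

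Each comparison used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the log2 level or index with 1 mean per group of cultures. The residual spread has 4 degrees of freedom, all from wild type. p values were adjusted over all genes of a comparison (Benjamini-Hochberg) with a threshold of 0.05. Tests that involve gcn2D assume that its lone cultures vary as wild type cultures do, and the gcn2D response itself is a value with no test. Where a probe was above background on no array of a group, the smallest change that the background allows was computed and is written as "at least". An exact test of 3 against 3 cultures cannot give a p below 0.1, so the calls rest on limma's pooling of the spread over genes.

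The 28 gene lists were fixed with that design: histidine; arginine and ornithine; lysine; branched-chain; aromatic; methionine, cysteine and sulfate; and glutamate-to-asparagine synthesis, amino acid transport, aminoacyl-tRNA synthetases, eIF2 with eIF2B, eIF2 kinases and Fil1, other translation factors, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, core stress response, heat shock and chaperones, proteasome, glycolysis and fermentation, respiration and the TCA cycle, iron uptake and iron-sulfur, histones, cell cycle and replication, nitrogen starvation with mating and meiosis, purine and pyrimidine synthesis, autophagy and TOR signalling, mitochondrially encoded transcripts, small noncoding RNA and long noncoding RNA. No mitochondrially encoded transcript was on the array, which left 27 lists. The small noncoding RNA list was matched by name patterns that can also fit protein-coding genes. The arginine and ornithine list also holds car1, car2 and aru1, which act in arginine breakdown, so it is not a list of synthesis alone. Lists were tested against the other genes with camera (preset correlation 0.01, adjusted over the lists), again with the correlation estimated from the residuals, and with fry, which asks only whether a list moves on balance. The genes named in each comparison were fixed by rule: always gcn2, fil1 and his5; among genes past the threshold, and in wild type with all 3 treated cultures on 1 side of all 3 untreated ones, the 8 largest rises and 8 largest falls; from each list past the threshold, the 3 members with the largest change in its direction; where no gene passed, the 4 smallest p values in each direction; and for the untreated profile, the 5 highest and 5 lowest coding genes with a symbol. Genes outside the rule are said to have been chosen after their values were seen.

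Precision is limited by the number of arrays. Between 73.13 and 78.66% of gene probes were well above background on total RNA arrays, and between 13.26 and 74.8% on fraction arrays. The median SD between the spots of a probe was 0.0654 to 0.096 (log2) for total RNA and 0.089 to 0.209 for fractions, and no probe was saturated. Simulated changes were added to wild type noise to test each step. In total RNA (5087 genes), log2 changes of 1 and 2 were recovered in 83 and 96% of changed genes for the wild type comparison, 16 and 68% for the difference between genotypes, and 62 and 88% for untreated gcn2D against wild type. For the index (3543 genes), recovery was 44 and 94%, 0 and 0%, and 6 and 68%. At most 4.55% of calls were false in this noise, which was drawn for each gene alone, without shifts shared within a culture. Real wild type pairs put in the place of the gcn2D pair gave calls in both measures, so the real rate can be higher. A list shifted by log2 1 was found in 100% of 20 simulations, and 0 or 0.2% of the other lists were called. That rate is for simulated noise. In the 9 wrong splits of the real wild type cultures camera called 4 to 17 of 27 lists in total RNA and 3 to 11 for the index. The real split gave 13 and 10. Each wrong split has treated and untreated cultures in both groups and keeps part of the treatment difference, so its calls need not be false.

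Alternatives covered the scaling (quantile, median of detected genes, normexp with an offset of 50, the authors' value table, the array spike-ins, the percentile over all probes), the filter on dim probes, eBayes with trend and robust settings, the definition of the index, a replicate block, 1 fit over all 56 fraction arrays, a 1.5-fold minimum, and leaving out each wild type culture in turn. Whether the culture numbers pair treated with untreated cultures stayed open. The correlation of same-number deviations was 0.34, 0.351 and -0.0413 in total RNA, where replicates 1 and 2 were closest to their own number. For the index it was -0.34, -0.0127 and 0.0619, and no replicate was closest to its own number. A block on the numbers was kept as an alternative only. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6. Tables were handled with version 1.17.8 of data.table and 2.0.0 of jsonlite.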

Results

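RNA was measured in wild type and gcn2D fission yeast without treatment and after 30 min of 3AT, an inhibitor of histidine synthesis, in medium without histidine. Untreated cells had histidine in their medium, so 3AT here stands for the drug and the medium together. In each of 8 cultures the arrays covered total RNA and 7 polysome gradient fractions. The series title gives the setting: the Gcn2 kinase, which phosphorylates eIF2 alpha when amino acids run short, and motifs and upstream open reading frames in 5′ leaders of the mRNAs it affects. Wild type had 3 cultures per condition and gcn2D had 1, so gcn2D values have no replicate. Total RNA levels correlated at 0.971 to 0.994 between wild type cultures of the same condition and at 0.91 to 0.941 between conditions, across 5087 genes that are not independent replicates. For the polysome index the ranges were 0.872 to 0.963 and 0.753 to 0.947 across 3543 genes. The median index of a culture was -1.065, -0.593 and -0.323 in untreated wild type, -0.0687, -0.284 and -0.0729 after 3AT, and -0.503 and -0.366 in untreated and treated gcn2D. Each culture was hybridized on its own slide, so slide and culture cannot be told apart. The gcn2 probe was above background on none of the 16 gcn2D arrays and on every wild type total RNA array.

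One comparison asked how total RNA of wild type cells changed with 3AT. gcn2 mRNA itself (SPBC36B7.09, chromosome 2, 2396675 to 2401454) rose 4.16-fold, a log2 change of 2.06 ± 0.23 (SE, 3 cultures against 3, limma adjusted p = 0.00101). Among genes whose rise has an exact size, the largest was in ecl1 (SPCC70.12c, chromosome 3, 2355545 to 2355787), a small gene that extends chronological lifespan when overexpressed, at 81.4-fold (6.35 ± 0.3, limma adjusted p = 5.67e-05). The predicted urea transporter SPBC23G7.13c (chromosome 2, 2123260 to 2125254) rose at least 46.7-fold, and the invertase gene inv1 (SPCC191.11, chromosome 3, 1724306 to 1726051) rose at least 20.8-fold. The genes that fell most included the hexose transporter gene ght5 (SPCC1235.14, chromosome 3, 212313 to 213953), which fell 9.79-fold (-3.29 ± 0.43), the copper transporter gene ctr4, which fell 6.27-fold (-2.65 ± 0.57), and the chaperone gene hsp90, which fell 5.71-fold (-2.51 ± 0.46). Of 5087 genes, 2514 passed the threshold, 1105 higher and 1409 lower, and 1584 did so with at least a 1.5-fold change. Which side was larger depended on the scaling, with 1210 higher and 1149 lower at the median of detected genes and 856 and 1293 with normexp. The treated and untreated cultures did not overlap in 61.4% of genes, against 10% on average by chance. Genes of a culture can move together, so that share is not a test. In every gene named in this comparison as past the threshold, all 3 treated cultures lay on the same side of all 3 untreated ones.

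Among the other large rises, ddr48 and lsd90, both known as stress-induced genes, rose 71.8-fold (6.17 ± 0.83) and 60.6-fold (5.92 ± 0.82). Their untreated gcn2D levels, 3.27 and 2.41, stood near the treated wild type levels of 3.68 and 3.04. The noncoding RNA SPNCRNA.79 rose at least 16.8-fold, the noncoding RNA SPNCRNA.1255 rose 40.3-fold (5.33 ± 0.63), and the predicted methyltransferase gene SPCC70.08c rose 32.2-fold (5.01 ± 0.39). Among the other large falls were mei2, the RNA-binding switch gene of meiosis, at 7.3-fold (-2.87 ± 0.52) and the noncoding RNAs SPNCRNA.949, SPNCRNA.106 and SPNCRNA.532 at 6.91-, 6.15- and 5.69-fold. The peptidase C26 family gene SPBPB2B2.05 fell at least 2.07-fold. Adjusted p for these genes ran from 5.67e-05 for ecl1 to 0.00868 for ctr4, apart from SPBC23G7.13c at 4.46e-07. The transcription factor gene fil1 (SPCC1393.08, chromosome 3, 812655 to 814328) had a log2 change of 0.48 ± 0.19 that did not pass (adjusted p = 0.0772). The histidine synthesis gene his5 (SPBC21H7.07c, chromosome 2, 2266666 to 2267316) fell by 0.31 ± 0.11 with an adjusted p of 0.0496, just inside the threshold. Under 16 alternatives its adjusted p ran from 0.0329 to 0.287 and passed in 5. For fil1 the range was 0.0211 to 0.227, with 3 of 16 past.

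**Figure D1:**
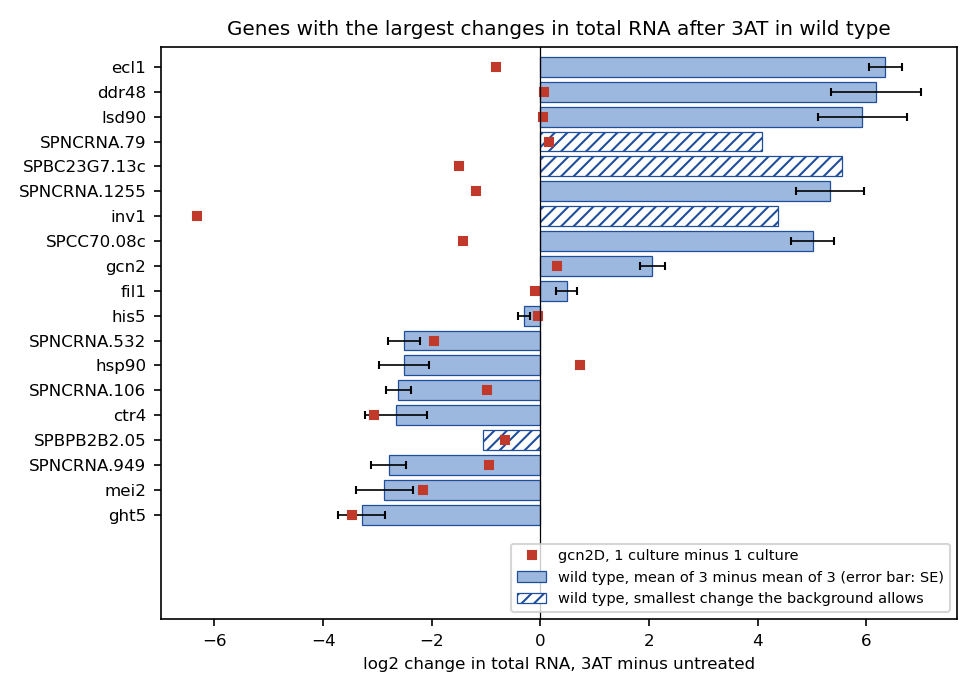
Bars give the log2 change in total RNA after 3AT in wild type for gcn2, fil1, his5 and the genes with the largest rises and falls (error bars: SE, 3 cultures against 3; hatched bars: smallest change the background allows), and squares give the gcn2D difference of 1 culture against 1. ecl1 stands at 6.35 in wild type and -0.81 in gcn2D, and ght5 at -3.29 and -3.46.

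Among the lists of amino acid synthesis, those of arginine and of branched-chain amino acids passed camera upward. Of 12 measured genes of the arginine and ornithine list, 6 rose and 2 fell (9 and 2 adjusted over the list alone), with a median log2 change of 0.575 (camera adjusted p = 0.0469, and adjusted p = 0.704 with an estimated correlation). These values cover the breakdown genes car1, car2 and aru1 along with the synthesis genes, here and wherever the list is named below. The carbamoyl-phosphate synthase genes arg5 (SPBC56F2.09c, chromosome 2, 4094648 to 4095895) and arg4 rose 3.2-fold (1.68 ± 0.32) and 2.99-fold (1.58 ± 0.26), and the ornithine carbamoyltransferase gene arg3 rose 2.57-fold (1.36 ± 0.33). Of 9 branched-chain synthesis genes, 5 rose and 0 fell, by both adjustments, with a median of 0.485 (camera adjusted p = 0.0368, adjusted p = 0.661 with an estimated correlation). They included leu3, for isopropylmalate synthase, at 2.78-fold and leu2 at 2.04-fold. Histidine synthesis (7 genes, 4 higher and 2 lower, adjusted p = 0.286), lysine (7, 3 and 1, 0.128), aromatic amino acids (8, 3 and 1, 0.155), glutamate to asparagine (18, 10 and 3, 0.1) and amino acid transport (14, 4 and 0, 0.1) did not pass camera, and their counts adjusted over the list alone were the same. Their medians were 0.349, 0.465, 0.207, 0.481 and 0.22. Methionine, cysteine and sulfate assimilation had 3 of 23 genes higher and 7 lower by both adjustments and a median of -0.332 (adjusted p = 0.213).

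Autophagy and TOR signalling genes, which serve self-digestion and nutrient sensing, had 24 of 49 members higher and 0 lower by both adjustments (median 0.37, camera adjusted p = 1.19e-06, adjusted p = 0.475 with an estimated correlation). The kinase regulator gene atg13 rose 2.69-fold (1.43 ± 0.11) and the Atg8 protease gene atg4 rose 2.78-fold (1.47 ± 0.14). The core stress response list had 27 of 57 genes higher and 8 lower (28 and 10 adjusted over the list alone), with a median of 0.65 and a mean of 1.01 (camera adjusted p = 0.000982, adjusted p = 0.661 with an estimated correlation). It included rds1 at 29.7-fold (4.89 ± 0.54) and the calcium ATPase gene cta3 at a bound of at least 3.98-fold. Of 11 histone genes 7 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.397, camera adjusted p = 0.0432, adjusted p = 0.661 with an estimated correlation), among them hht2 at 1.43-fold and htb1 at 1.32-fold. Of 354 long noncoding RNAs 145 rose and 43 fell (146 and 46 adjusted over the list alone, median 0.439, camera adjusted p = 9.88e-07, adjusted p = 0.661 with an estimated correlation), with SPNCRNA.517 up at least 9.2-fold. The size depends on the processing, as with normexp their median was 0.0499, and relative to all genes it was 0.14 in place of 0.53.

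Lists of ribosomal proteins, ribosome biogenesis, translation factors and tRNA synthetases passed camera downward. Of 140 cytosolic ribosomal protein genes, 124 fell and 1 rose (127 and 1 adjusted over the list alone), with a median of -0.564 (camera adjusted p = 2.58e-16, adjusted p = 0.661 with an estimated correlation), but with quantile normalization their median was -0.0784, which is 0.0291 above the median of all genes. These genes are bright: in fraction 1 of untreated wild type replicate 1 their median level was 3.66, against -4.452 for coding genes. Quantile normalization gives the brightest genes of every array the same levels. It would remove a shared change of such genes, so here and below it cannot decide whether they changed. The largest falls were in rpl1603 (3.03-fold), rpl44 (2.41-fold) and rps2802 (2.06-fold). Of 54 mitochondrial ribosomal protein genes 32 fell and 0 rose by both adjustments (median -0.385, camera adjusted p = 7.74e-05, adjusted p = 0.661 with an estimated correlation), led by img1 at 2.35-fold and mrpl19 at 2.27-fold. Of 108 ribosome biogenesis genes 41 fell and 3 rose by both adjustments (median -0.308, camera adjusted p = 0.00313, adjusted p = 0.724 with an estimated correlation). nop12 and nop9, RNA-binding proteins of the nucleolus, fell by 1.01 ± 0.13 and 0.85 ± 0.13 (log2). lsg1, which fell 2.26-fold, is annotated in the files as a subunit of the Lsk1 kinase complex rather than as a ribosome biogenesis factor. The release factor gene erf1 fell 1.74-fold and tma20 fell 1.84-fold among 32 other translation factors, of which 16 fell and 1 rose by both adjustments (median -0.316, camera adjusted p = 0.00669, adjusted p = 0.56 with an estimated correlation). Of 19 aminoacyl-tRNA synthetase genes 11 fell and 0 rose by both adjustments (median -0.356, camera adjusted p = 0.0394, adjusted p = 0.661 with an estimated correlation), including qrs1 at 2.1-fold and wrs1 at 1.7-fold.

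Of 30 heat shock and chaperone genes 13 fell and 1 rose by both adjustments (median -0.379, camera adjusted p = 0.00834, adjusted p = 0.704 with an estimated correlation), with the Hsp90 partner wos2 down 3.18-fold and the DnaJ protein gene mas5 down 3.11-fold. Of 19 genes of glycolysis and fermentation 14 fell and 3 rose by both adjustments (median -0.8, camera adjusted p = 0.0119, adjusted p = 0.475 with an estimated correlation), including adh1, for alcohol dehydrogenase, at 2.91-fold and pgk1 at 2.79-fold, but with quantile normalization their median was -0.27, and relative to all genes it was -0.163 in place of -0.709. The remaining lists did not pass camera. The list of eIF2, its exchange factor and its kinases had 2 of 19 members higher and 6 lower by both adjustments (adjusted p = 0.347), purine and pyrimidine synthesis 0 of 21 higher and 4 lower (0 and 3 adjusted over the list alone, adjusted p = 0.162), and the proteasome 1 of 33 higher and 11 lower (0 and 9 adjusted over the list alone, adjusted p = 0.0529). Iron uptake had 6 of 19 higher and 4 lower (6 and 5 adjusted over the list alone, adjusted p = 0.104) and cell cycle genes 5 of 41 higher and 11 lower (4 and 7 adjusted over the list alone, adjusted p = 0.478). Nitrogen starvation, mating and meiosis had 9 of 30 higher and 3 lower by both adjustments (adjusted p = 0.1), with a median of 0.165 that became -0.00626 with normexp. Respiration had 8 of 52 higher and 8 lower (7 and 7 adjusted over the list alone, adjusted p = 0.794), with a median of -0.0703, a mean of 0.0155 and a test direction above the other genes. The list of small noncoding RNAs had 2 of 9 higher and 2 lower by both adjustments (adjusted p = 0.957), with a median of -0.00933, a mean of 0.2 and a median of 0.0539 when scaled to the median of detected genes. Its name patterns can also fit protein-coding genes. Before treatment its 6 members with an index stood at 0.282 from the median coding gene, against -2.22 for noncoding RNAs, so it may hold coding genes. No list passed with an estimated correlation, where adjusted p ran from 0.475 to 0.958, and 12 of 27 passed with fry. Wrong splits of the same 6 cultures, which keep part of the treatment difference, gave up to 17 lists by camera, against 13 for the real one. Scaled to the spike-ins, 1467 genes passed in place of 2514. htb1 lost its call under 6 alternatives, and hht2 with spike-in scaling and without untreated replicate 3.

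**Figure D2:**
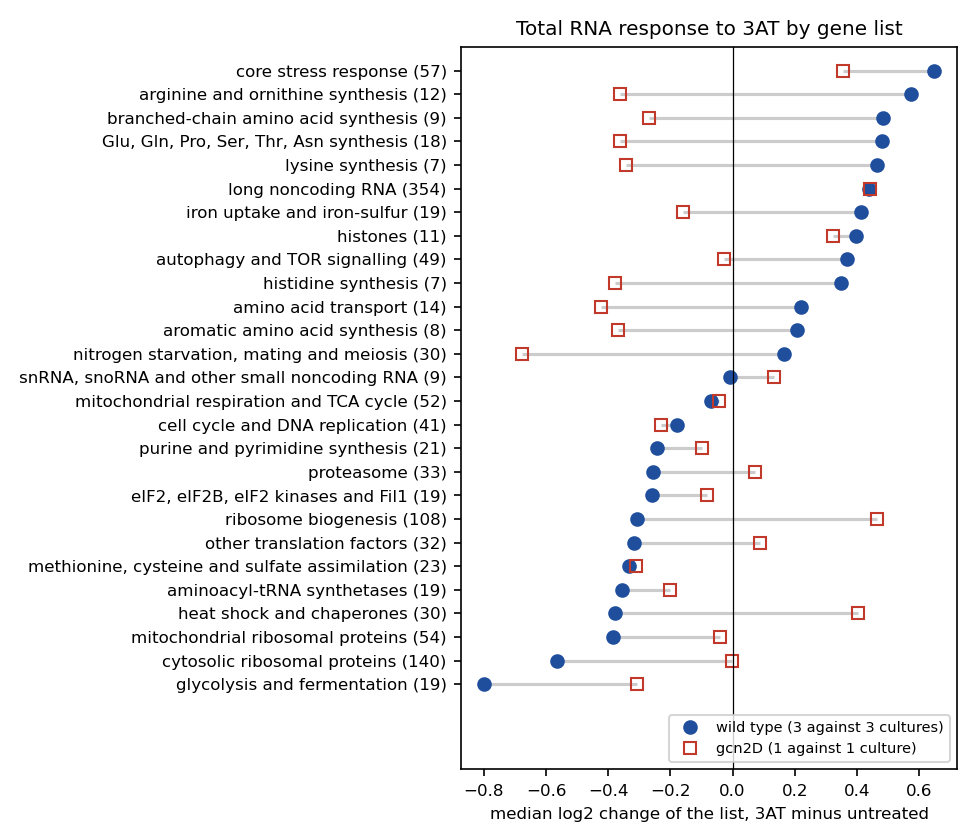
Points give the median log2 change in total RNA after 3AT of each gene list (number of measured genes in brackets) in wild type (filled circles, 3 cultures against 3) and gcn2D (open squares, 1 against 1, no test). The arginine list, which includes breakdown genes, stands at 0.575 and -0.361, and ribosome biogenesis at -0.308 and 0.465. With spike-in scaling the gcn2D median of the arginine list is 0.322. With quantile normalization, which would remove a shared fall of the brightest genes, the wild type median of cytosolic ribosomal proteins lies 0.0291 above that of all genes.

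The next comparison asked which total RNA responses to 3AT differed when Gcn2 was missing. The response in gcn2D was lower for ecl1 (-0.81 against 6.35 in wild type, a difference of -7.16 ± 0.59, limma adjusted p = 0.00402), for SPBC23G7.13c (difference -7.16 ± 0.2, adjusted p = 1.21e-05) and for inv1 (difference -11.44 ± 0.62, adjusted p = 0.000609). aca1, which encodes an acetyltransferase that detoxifies azetidine-2-carboxylic acid, differed by -6.07 ± 0.69, SPCC70.08c by -6.43 ± 0.77, wwm3 by -6.25 ± 1.02, SPNCRNA.1255 by -6.51 ± 1.26 and SPNCRNA.79 by -5.73 ± 0.74. The response in gcn2D was higher for zpr1, whose product binds the elongation factor EF-1 alpha, by 3.27 ± 0.46 (adjusted p = 0.0262), for mas5 by 3.01 ± 0.58 (adjusted p = 0.0452), for the RNAs SPNCRNA.1405 and SPNCRNA.1653 by 3.94 ± 0.53 and 3.74 ± 0.32, for SPNCRNA.1154, SPNCRNA.1005 and SPNCRNA.1153 by 2.98, 2.96 and 2.69, and for SPBC1685.12c by 2.35. The test sets 1 gcn2D culture per condition against 3 of wild type and assumes that it varies as wild type does. Of 5087 genes 153 passed, 41 with a higher and 112 with a lower response in gcn2D. Most of the 112 had risen in wild type, with a median of 1.83 in wild type and -0.496 in gcn2D. The wild type response is part of the difference, so this overlap follows in part from the test itself. The values of inv1, SPBC23G7.13c, wwm3, SPNCRNA.79, SPNCRNA.1405, SPNCRNA.1154 and SPNCRNA.1005 include groups with no array above background and are fitted values, not fold changes. fil1 (-0.58 ± 0.39, limma adjusted p = 0.38) and his5 (0.26 ± 0.22, 0.481) did not pass. gcn2 did not either (-1.74 ± 0.46, adjusted p = 0.081), but its probe was above background on no gcn2D array, so that value has no meaning as a response.

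The count depended on single cultures. It was 58, 21 or 30 without untreated wild type replicate 1, 2 or 3 and 309, 301 or 29 without treated replicate 1, 2 or 3. Of the named genes, inv1, SPBC23G7.13c, ecl1 and SPNCRNA.1653 passed under each alternative run. Scaled to the spike-ins, the median difference of all genes moved from 0.0825 to 0.806 and 597 genes passed, 84.9% of them with a higher response in gcn2D against 26.8% here. With no filter on dim probes 84 genes passed, and with trend and robust settings 298. Of the 1105 genes that rose in wild type, 61.6% also had a positive value in gcn2D (47.7% of all genes did), with medians of 0.862 and 0.158. Of the 1409 that fell, 69.7% had a negative value in gcn2D (52.3% of all genes did), with medians of -0.603 and -0.144. These signs in gcn2D rest on the scaling of 1 culture against 1. Spike-in scaling raises all gcn2D values alike, and takes the median of arginine synthesis from -0.361 to 0.322.

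By list, medians below are relative to the median of all genes. None of their directions flipped under the scalings run, but some sizes fell far. With quantile normalization, which would remove a shared change of the brightest genes, cytosolic ribosomal proteins went from 0.487 to 0.00582. Other translation factors went from 0.258 to 0.131 with it. With normexp nitrogen starvation genes went from -0.938 to -0.186, amino acid transport from -1.11 to -0.539, autophagy from -0.581 to -0.371 and the proteasome from 0.183 to 0.107. The 7 lists of amino acid supply other than methionine and cysteine passed camera with lower responses in gcn2D. Arginine synthesis stood at -1.06 (camera adjusted p = 0.00195, adjusted p = 0.507 with an estimated correlation), lysine at -1.05 (0.0171, 0.507), branched-chain at -0.701 (0.0059, 0.507), aromatic at -0.9 (0.0138, 0.507), histidine at -0.458 (0.0281, 0.581), glutamate to asparagine at -0.83 (0.00193, 0.581) and amino acid transport at -1.11 (0.000287, 0.507), giving each list's camera adjusted p and then its adjusted p with an estimated correlation. By gene, his4 of histidine synthesis (-2.22 ± 0.44, adjusted p = 0.0476), lys3 of lysine synthesis (-1.78 ± 0.29, 0.0315) and pha2 of phenylalanine synthesis (-1.14 ± 0.22, 0.0464) passed. arg5 (-2.08, 0.103), leu3 (-1.89, 0.075), asn1, for asparagine synthetase (-2.36, 0.0517), and cat1, a cationic amino acid transporter (-1.97, 0.0517), did not. Counts of lower responses over all genes and adjusted over the list alone were 0 and 7 for arginine, 1 and 2 for lysine, 0 and 2 for branched-chain, 1 and 4 for aromatic, 1 and 3 for histidine, 1 and 7 for glutamate to asparagine and 1 and 6 for transport. Lysine and glutamate to asparagine also had 1 higher gene each adjusted over the list alone.

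Autophagy and TOR signalling (-0.581, camera adjusted p = 4.5e-07, adjusted p = 0.412 with an estimated correlation) had 2 lower genes, atg43 (-2.8 ± 0.46) and atg2402 (-2.73 ± 0.53), and 18 adjusted over the list alone. Nitrogen starvation, mating and meiosis (-0.938, 3.53e-05, adjusted p = 0.412 with an estimated correlation) had 2 and 8, with the ammonium transporter genes amt1 and amt3 at -2.91 and -2.95 and not past. Iron uptake (-0.653, 0.00195, adjusted p = 0.507 with an estimated correlation) had 0 and 2, and core stress genes (-0.315, 0.0423, adjusted p = 0.795 with an estimated correlation) 0 and 4, with 1 higher adjusted over the list alone. Higher responses in gcn2D were found for ribosome biogenesis (0.605, camera adjusted p = 2.41e-16, adjusted p = 0.507 with an estimated correlation), with 5 higher genes over all genes, among them nop12 (1.53 ± 0.25), brx1 (1.34 ± 0.23) and nop9 (1.3 ± 0.26), and 41 adjusted over the list alone. Heat shock and chaperone genes (0.749, 7.56e-06, adjusted p = 0.507 with an estimated correlation) had 1 and 10, and hsp104, hsp78 and ssa1 had gcn2D responses of 3.46, 3.4 and 2.74 with differences that did not pass. Cytosolic ribosomal proteins (0.487, but 0.00582 with quantile normalization, 1.99e-14, adjusted p = 0.507 with an estimated correlation) had 1 and 0, mitochondrial ribosomal proteins (0.231, 0.00229, adjusted p = 0.507 with an estimated correlation) 0 and 0, other translation factors (0.258, 0.00903, adjusted p = 0.507 with an estimated correlation) 0 and 2, with 1 lower by both, and the proteasome (0.183, 0.0441, adjusted p = 0.859 with an estimated correlation) 0 and 0. Of 27 lists 17 passed camera, 0 with an estimated correlation (adjusted p from 0.412 to 0.957), and 3 with fry, namely amino acid transport, other translation factors and autophagy.

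Untreated gcn2D and wild type were compared next. gcn2 mRNA was at least 23.7-fold lower in gcn2D (limma adjusted p = 0.000647), a check of the genotype labels. inv1 was at least 61.8-fold higher (adjusted p = 0.00155), agl1 (SPAPB24D3.10c, chromosome 1, 2968079 to 2970988), for alpha-glucosidase, was 39.5-fold higher (5.3 ± 0.29, adjusted p = 0.000647) and ght4 (SPBC1683.08, chromosome 2, 157555 to 159228), for a hexose transporter, was 4.74-fold higher (2.25 ± 0.22, adjusted p = 0.0169). After 3AT these genes of sugar uptake and use had gcn2D responses of -6.32, -4.2 and -3.18. These 4 of 5087 genes were past the threshold, with 1 gcn2D culture against 3 of wild type, and 262 had an unadjusted p under 0.05. fil1 (0.04 ± 0.27, adjusted p = 0.994) and his5 (-0.35 ± 0.15, adjusted p = 0.908) did not pass. The count was 40 without treated wild type replicate 2, 7 without treated replicate 1 and 21 when scaled to the spike-ins, where the median of all genes moved from -0.0486 to -0.597. ght4 lost its call without untreated replicate 2 or treated replicate 3 (adjusted p = 0.0815 and 0.0994).

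Core stress genes were higher in untreated gcn2D (median 0.389, camera adjusted p = 1.72e-13, adjusted p = 0.392 with an estimated correlation), with lsd90 at 5.29 ± 1.16 and hsp16 at 5.0 ± 1.18, though no member passed over all genes or adjusted over the list alone. Autophagy (0.112, 8.12e-06, adjusted p = 0.389 with an estimated correlation), nitrogen starvation with mating and meiosis (0.18, 1.11e-05, adjusted p = 0.341 with an estimated correlation), amino acid transport (0.0735, 0.00683, adjusted p = 0.446 with an estimated correlation) and iron uptake (0.11, 0.0199, adjusted p = 0.618 with an estimated correlation) were also higher, and all 5 medians were negative with spike-in scaling but above that of all genes. Relative to all genes, normexp lowered nitrogen starvation from 0.229 to 0.127 and transport from 0.122 to 0.0779, and quantile normalization moved other translation factors, named next, from -0.149 to -0.0826. Over all genes and adjusted over the list alone, nitrogen starvation had 1 and 3 higher genes, transport 0 and 1, and autophagy and iron uptake 0 and 0. Ribosome biogenesis (-0.239, camera adjusted p = 2e-11), other translation factors (-0.198, 9.57e-05), the eIF2 list (-0.202, 0.00683) and mitochondrial ribosomal proteins (-0.126, 0.00683) were lower, with adjusted p = 0.608, 0.341, 0.446 and 0.608 with an estimated correlation. Cytosolic ribosomal proteins were lower as well (-0.276, camera adjusted p = 5.85e-18, adjusted p = 0.608 with an estimated correlation), but lay 0.0114 above all genes with quantile normalization. Apart from gcn2 in the eIF2 list, 0 members of these 5 lists passed in limma over all genes or adjusted over the list alone. With fry 0 lists passed.

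Before treatment, wild type mRNAs differed widely in where they sat in the gradient. Values here are the index minus the median of protein-coding genes in the same culture (mean ± SD, n = 3). Glycolysis and fermentation genes stood at 1.32 ± 0.604, arginine synthesis at 0.963 ± 0.13, purine and pyrimidine synthesis at 0.886 ± 0.183, heat shock genes at 0.858 ± 0.0931, histidine synthesis at 0.847 ± 0.0438 and aminoacyl-tRNA synthetases at 0.651 ± 0.0921, toward the high fraction numbers. Cytosolic ribosomal proteins at -0.478 ± 0.316, autophagy genes at -0.559 ± 0.086 and 60 noncoding RNAs at -2.22 ± 0.197 stood toward the low numbers. The highest coding genes were wwm2 (2.52 ± 0.93), his5 (2.26 ± 0.17), the superoxide dismutase gene sod1 (2.19 ± 0.67), the 14-3-3 gene rad24 (2.16 ± 0.49) and snz1 of pyridoxine synthesis (2.05 ± 0.57). The lowest were the ribosomal protein genes rpl39 (-3.82 ± 0.24) and rps2802 (-3.28 ± 0.08), trs130 of a vesicle tethering complex (-3.42 ± 0.16), fta6 (-3.4 ± 0.42) and sws1 (-3.31 ± 0.17). fta6 was above background on 13 of 21 fraction arrays. Spearman's rho of the index with the coding span, introns included, averaged 0.053 ± 0.0534 over the 3 cultures, and the fifth of genes with the shortest spans (99 to 708 nt, 690 genes) stood at -0.216 ± 0.0766.

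The polysome index asked which mRNAs moved along the gradient in wild type with 3AT. The index of fil1, the GATA-type transcription factor gene, rose by 1.39 ± 0.32 (2.61-fold, limma adjusted p = 0.021), from -0.62 ± 0.64 to 0.76 ± 0.27 (SD, n = 3). By fraction, fil1 was higher in fraction 6 (1.62 ± 0.37, adjusted p = 0.0201) and fraction 7 (1.18 ± 0.29, 0.0475), and in fractions 1 to 5 its values were 0.31, -0.63, 0.89, 1.24 and 1.93, none past the threshold. gcn2 (0.5 ± 0.29, adjusted p = 0.19) and his5 (0.18 ± 0.28, adjusted p = 0.616) did not pass. Rises were found for hsp3101, a stress-induced glyoxalase-like gene (2.25 ± 0.35), the glyoxylate reductase gene gor2 (2.2 ± 0.39), the alanine racemase gene SPAC1039.06 (2.19 ± 0.34), aca1 (1.89 ± 0.42), the uridine hydrolase gene urh1 (1.77 ± 0.35), the TFIIE subunit gene tfa2 (1.75 ± 0.34), dms1 (1.69 ± 0.32) and the sugar reductase gene SPAP32A8.02 (2.58 ± 0.41), with adjusted p from 0.00182 to 0.0191. The last rests on early fractions where its probe was above background on 0 of 9 treated arrays. The index fell for the G protein beta subunit gene gnr1 (-1.49 ± 0.32), for coa3 (-1.23 ± 0.32) and for a phosphoketolase gene, SPBC24C6.09c (-1.02 ± 0.3). The gnr1 and coa3 probes were above background on 8 and 7 of 21 untreated arrays.

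Of 3543 genes 277 passed, 271 higher and 6 lower, with a median change of 0.518 over all genes. The groups did not overlap in 43.6% of genes against 10% on average by chance. The median index of every treated culture (-0.0687, -0.284 and -0.0729) lay above that of every untreated one (-1.065, -0.593 and -0.323). A shift shared by all genes sets many of them apart at once, so that share is no evidence about single genes. The count of 277 rests on the scaling. It was 0 when each array was scaled to its own 75th percentile over all probes (median 0.0385), the scaling that the design had named, 0 with spike-in scaling (0.711), 0 with each culture centred on its median, 4 with quantile normalization (2 of them higher, median 0.0111), 44 with the median of detected genes and 42 with normexp (0.0962), against 1328 genes with an unadjusted p under 0.05 in limma at the main scaling. With the value table of the authors, scaled in the main way, it was 299 (294 higher, 5 lower, median 0.505), of which 259 were shared. It was 70, 306 and 1431 without untreated replicate 1, 2 or 3 and 26, 87 and 0 without treated replicate 1, 2 or 3. The fil1 rise had adjusted p from 6.61e-05 to 0.702 over 24 alternatives and passed in 14. It was 0.9 with quantile normalization (adjusted p = 0.152), 0.91 with the all-probe percentile (0.148) and 0.87 after centring (0.136), and it also missed the threshold without treated replicate 1 (0.0746) or 3 (0.116). The other genes named here as past the threshold all lost their calls with spike-in scaling, with the all-probe percentile, after centring and without treated replicate 3. Spike-in scaling moves all genes of a culture alike and took the median change from 0.518 to 0.711. The named rises were thus not smaller with it, and their lost calls there are not a loss of size.

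**Figure D3:**
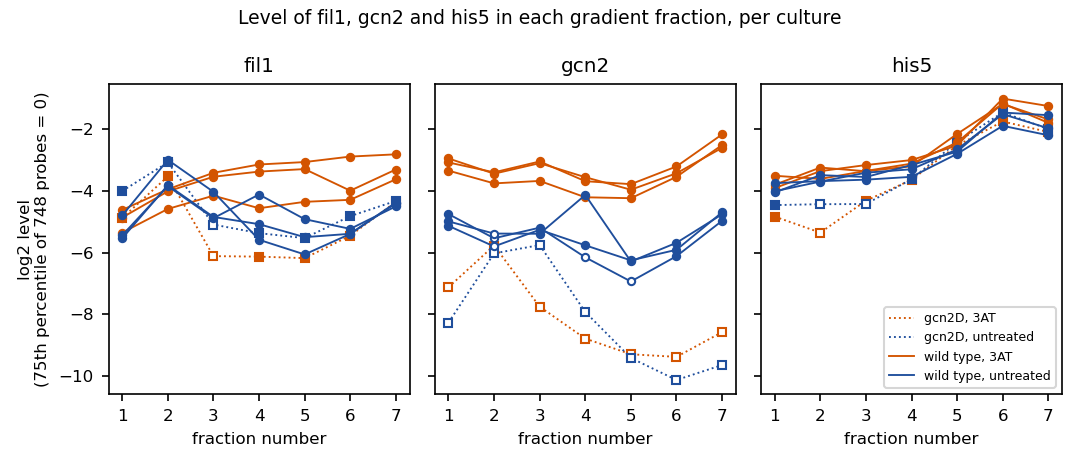
Lines give the log2 level of fil1, gcn2 and his5 in fractions 1 to 7, with 1 line per culture (3 per condition in wild type, 1 in gcn2D). Levels are scaled so that the 75th percentile of 748 probes is 0, and open markers are points not above background. After 3AT, fil1 is higher in wild type by 1.62 in fraction 6, and gcn2 by 1.84 to 2.51 in fractions 1, 3, 5, 6 and 7; in fraction 2 its untreated probe was above background on 0 of 3 wild type arrays.

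**Figure D4:**
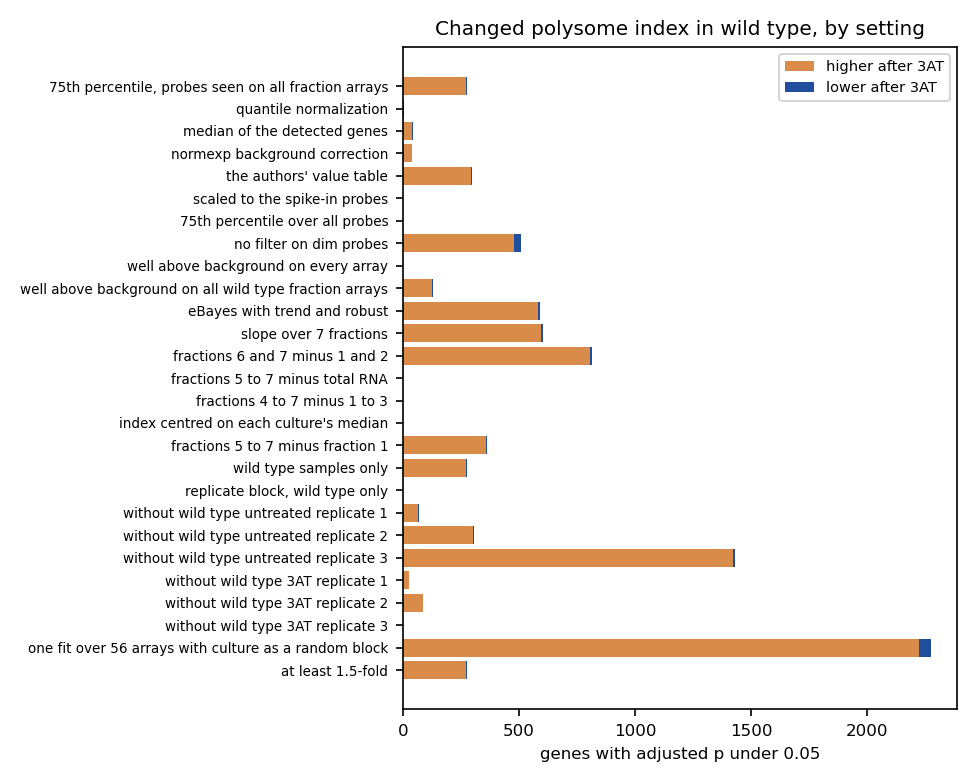
Bars give the number of genes with an adjusted p under 0.05 for the change of the polysome index after 3AT in wild type under each way of processing. The count is 277 at the main scaling, 0 with the percentile over all probes and 1431 without untreated replicate 3.

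Relative to other genes, camera placed 10 of 27 lists lower in index after 3AT, and 0 of them passed with an estimated correlation. Cytosolic ribosomal proteins stood -0.519 below the median of all genes (camera adjusted p = 1.31e-28, adjusted p = 0.616 with an estimated correlation), with a median of -0.000566 and a mean of 0.0288. Glycolysis stood at -0.573 (1.95e-09, 0.602), heat shock genes at -0.515 (5.33e-10, 0.602), aminoacyl-tRNA synthetases at -0.488 (2.92e-07, 0.788), purine and pyrimidine synthesis at -0.421 (1.04e-06, 0.616) and methionine, cysteine and sulfate assimilation at -0.273 (0.0153, 0.788), giving camera's adjusted p and then the adjusted p with an estimated correlation. These sizes rest on the processing. With normexp ribosomal proteins stood at -0.0828, aminoacyl-tRNA synthetases at -0.0846, purine synthesis at -0.132 and heat shock genes at -0.337, and with quantile normalization glycolysis stood at -0.0607 and methionine and cysteine at -0.0349. Arginine (-0.273, 0.0273, 0.788), aromatic (-0.37, 0.0486, 0.788), glutamate to asparagine (-0.233, 0.0241, 0.788) and branched-chain synthesis (-0.214, 0.0037, 0.616) were lower too, but with normexp these 4 stood at or above the median of all genes, and branched-chain synthesis also did so with quantile normalization. Apart from glycolysis and ribosomal proteins the medians of these lists were above 0 and the test direction was below the other genes, so the direction is a relative one. Members of the lists past the threshold over all genes were 2 lower ribosomal protein genes (1 adjusted over the list alone), 2 higher genes of methionine and sulfate assimilation (2) and 1 higher gene of branched-chain synthesis (1, with 1 lower), and 0 in the other lists by either adjustment in limma. ilv5 (-0.8 ± 0.29), pyk1, for pyruvate kinase (-0.65 ± 0.29), ura4 (-0.65 ± 0.28), ssa2 (-0.6 ± 0.31), rpl22 (-0.57 ± 0.28) and the phenylalanyl-tRNA synthetase gene frs1 (-0.54 ± 0.28) did not pass. With fry 0 lists passed.

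For the difference in index response between gcn2D and wild type, 0 of 3543 genes passed in limma, 96 had an unadjusted p under 0.05, and 0 to 3 passed when single wild type cultures were left out. The median difference of all genes was -0.382, and it was -0.0184 with quantile normalization, -0.753 with the median of detected genes, 0.162 with normexp, -0.794 with spike-in scaling and -0.00776 with the all-probe percentile. The fil1 response was 0.35 in gcn2D, a difference of -1.04 ± 0.64 from wild type (limma adjusted p = 0.954), so the fil1 rise was not shown to differ between genotypes. In fraction 3 the fil1 probe was not above background in either gcn2D culture, so these values are imprecise. The self-test recovered 0% of simulated differences here, even at a log2 change of 2. The smallest p values, none past the threshold, were in siw14 (-2.51 ± 0.66), urh2 (-2.37 ± 0.64), SPAC1039.06 (-2.39 ± 0.69) and pcr1 (-2.02 ± 0.62) on the lower side and coa3 (1.59), SPNCRNA.1376 (1.65), gnr1 (1.46) and SPBC24C6.09c (1.34) on the higher. Relative to all genes, camera placed aminoacyl-tRNA synthetases (0.619, adjusted p = 2.49e-05), heat shock genes (0.584, 7.15e-07), long noncoding RNAs (0.381, 6.3e-08), cytosolic ribosomal proteins (0.415, 8.37e-08), glycolysis (0.57, 0.000178), purine synthesis (0.327, 0.00274) and core stress genes (0.247, 0.045) higher in gcn2D, and mitochondrial ribosomal proteins (-0.363, 0.000591) and iron uptake (-0.383, 0.0279) lower, with ribosomal proteins, glycolysis and purine synthesis flipping with normexp and core stress genes with quantile normalization. The sizes rest on the processing as well: with normexp aminoacyl-tRNA synthetases stood at 0.0336 and mitochondrial ribosomal proteins at -0.0287, and with quantile normalization heat shock genes stood at 0.278. Each had an adjusted p = 0.853 with an estimated correlation, 0 of their members passed by either adjustment, and with fry 0 lists passed. The median of purine synthesis was -0.0552 with a mean of 0.00108. For cytosolic ribosomal proteins the median was 0.0327 with a mean of -0.0341, and for long noncoding RNAs -0.00109 with a mean of 0.0677. Core stress genes had a median of -0.135 against their upward test.

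Between untreated gcn2D and wild type, 1 gene of 3543 passed for the index, gcn2 at -2.59 ± 0.41, whose probe was above background on no gcn2D array, so the value has no meaning as a position, and 194 had an unadjusted p under 0.05. fil1 (-0.21 ± 0.45, limma adjusted p = 0.947) and his5 (0.87 ± 0.4, adjusted p = 0.818) did not pass. Relative to all genes, respiration genes (0.294, camera adjusted p = 3.71e-05, adjusted p = 0.962 with an estimated correlation) and the proteasome (0.228, 0.0236, adjusted p = 0.962 with an estimated correlation) stood higher in gcn2D. Long noncoding RNAs (-0.278, but -0.122 with normexp, 3.71e-05, adjusted p = 0.962 with an estimated correlation) stood lower, as did cytosolic ribosomal proteins (-0.522, 2.66e-16, adjusted p = 0.962 with an estimated correlation), which with normexp lay 0.375 above all genes. Over all genes 0 members passed in limma. Adjusted over the list alone 5 respiration genes were higher and 1 long noncoding RNA was lower. The ATP synthase gene atp17 (1.87 ± 0.43), the succinate dehydrogenase gene sdh2 (1.43 ± 0.43), the proteasome gene pre1 (1.23 ± 0.47), rpl101 (-0.81 ± 0.46) and SPNCRNA.134 (-2.03 ± 0.47) did not pass. The gene count was 100 with quantile normalization, 2486 with the median of detected genes and 2153 with normexp. The median of all genes, 0.15 here, was 1.23 and -0.621 with the last pair, 0.4 with spike-in scaling and -0.0733 with the all-probe percentile. With fry 0 lists passed.

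By fraction, gcn2 mRNA was higher after 3AT in wild type in fractions 1, 3, 5, 6 and 7, by 1.84 ± 0.2 to 2.51 ± 0.29 (limma adjusted p from 0.000282 to 0.00567). It passed in fraction 2 as well, but its untreated probe was above background there on 0 of 3 arrays, so the fitted value of 2.04 is not an exact size, and its fraction 4 value of 1.54 ± 0.52 did not pass (adjusted p = 0.352). his5 values lay between 0.2 and 0.5 in all 7 fractions and none passed. The numbers of genes past the threshold in fractions 1 to 7 were 146, 186, 179, 39, 109, 295 and 177 of 3543, of which 118, 118, 163, 39, 108, 289 and 175 were higher. The median change of all genes was -0.164, -0.334, -0.0416, 0.00229, 0.389, 0.392 and 0.296. A replicate block gave larger counts in fractions 1, 2, 3, 5, 6 and 7, listed in the part on processing. Without single cultures the counts ran from 65 to 125, 69 to 348, 97 to 254, 0 to 63, 0 to 150, 111 to 558 and 50 to 269. The lowest counts were without untreated replicate 3 for fractions 1 and 3, without untreated replicate 2 for fraction 2 and without treated replicate 1 for fractions 5 to 7, and the count in fraction 4 was 0 without untreated replicate 2 or any of the treated ones.

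Last, total RNA and index responses were set against each other across genes, which are not independent replicates. In wild type the correlation over 3543 genes was 0.203 (Spearman 0.19) and in gcn2D 0.376 (Spearman 0.391). Between genotypes it was 0.239 (0.291) for total RNA over 5087 genes and -0.0356 (-0.0728) for the index. In wild type, fil1 passed in the index and not in total RNA, and gcn2 passed in total RNA and not in the index.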

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

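The tests of the untreated level and of exposure to 3AT in the next paragraphs were chosen only after the result was seen. Each result in this part stood out because the total RNA or index response to 3AT differed between gcn2D and wild type when the difference itself was tested.

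A set of genes that rose in wild type had a lower response without Gcn2. The difference was -11.44 for the invertase gene inv1, -7.16 for the predicted urea transporter gene SPBC23G7.13c, -7.16 for the lifespan gene ecl1, -6.51 for SPNCRNA.1255, -6.43 for SPCC70.08c, -6.25 for wwm3, -6.07 for aca1 and -5.73 for SPNCRNA.79. In amino acid synthesis his4 stood at -2.22, lys3 at -1.78 and pha2 at -1.14, and in autophagy atg43 at -2.8 and atg2402 at -2.73. The response was higher in gcn2D for SPNCRNA.1405 by 3.94, SPNCRNA.1653 by 3.74, zpr1 by 3.27, the DnaJ gene mas5 by 3.01, SPNCRNA.1154 by 2.98, SPNCRNA.1005 by 2.96, SPNCRNA.1153 by 2.69 and SPBC1685.12c by 2.35, and in ribosome biogenesis for nop12 by 1.53, brx1 by 1.34 and nop9 by 1.3. For inv1, SPBC23G7.13c, wwm3, SPNCRNA.79, SPNCRNA.1405, SPNCRNA.1154 and SPNCRNA.1005 these are fitted values that include groups with no array above background, so their size and order cannot be read as fold changes. The total was 153 genes.

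The following list calls are camera's with its preset correlation. None passed with an estimated one, where adjusted p ran from 0.412 to 0.957 over the total RNA lists and was 0.853 for each index list named. By list and relative to all genes, total RNA responses were lower in gcn2D for amino acid transport (-1.11) and for synthesis of arginine (-1.06), lysine (-1.05), aromatic amino acids (-0.9), glutamate to asparagine (-0.83), branched-chain amino acids (-0.701) and histidine (-0.458). They were also lower for nitrogen starvation (-0.938), iron uptake (-0.653), autophagy (-0.581) and core stress genes (-0.315). They were higher for heat shock genes (0.749), ribosome biogenesis (0.605), cytosolic ribosomal proteins (0.487), other translation factors (0.258), mitochondrial ribosomal proteins (0.231) and the proteasome (0.183). Directions held under every scaling but sizes did not. With quantile normalization, which would remove a shared change of the brightest genes, cytosolic ribosomal proteins stood at 0.00582 and other translation factors at 0.131. With normexp nitrogen starvation stood at -0.186, amino acid transport at -0.539, autophagy at -0.371 and the proteasome at 0.107. For the index, aminoacyl-tRNA synthetases (0.619), heat shock genes (0.584), glycolysis (0.57), cytosolic ribosomal proteins (0.415), long noncoding RNAs (0.381), purine synthesis (0.327) and core stress genes (0.247) were higher and iron uptake (-0.383) and mitochondrial ribosomal proteins (-0.363) lower. With normexp the index direction of glycolysis, cytosolic ribosomal proteins and purine synthesis flipped, as did that of core stress genes with quantile normalization. With normexp aminoacyl-tRNA synthetases fell to 0.0336 and mitochondrial ribosomal proteins stood at -0.0287, and with quantile normalization heat shock genes stood at 0.278. For the index 0 members of these lists passed in limma, where 96 of all genes had an unadjusted p under 0.05, and with fry 0 lists passed.

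The 112 genes with a lower total RNA response in gcn2D were weighed as a pattern. A different starting level in the 1 untreated gcn2D culture was argued against for the set. The untreated difference of these genes had a median of 0.221 (SE 0.134), far smaller than their median difference in response of -2.39. However, inv1 and agl1 did start higher. That SE is over genes and is no spread between cultures, which 1 culture cannot give. The spread of a lone pair of cultures stays open. Of 9 wild type pairs put in the place of the gcn2D pair, 1 gave 71 genes and the other 8 gave 0. Against the same remaining cultures the gcn2D pair gave more genes each time, but only a few wherever treated replicate 3 was left out. A gcn2D culture that was not exposed to 3AT also cannot be told apart. The 164 genes that fell at least 2-fold in wild type had a gcn2D median of -0.538. Its SE of 0.0869, again over genes and not between cultures, spans the bound of -0.5 set for it. The loss of Gcn2 may contribute and remains an untested explanation, as each gcn2D condition has 1 culture.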

How the results depend on the processing

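The centred index, the filter on all wild type fraction arrays, fractions 5 to 7 minus fraction 1 and the spike-in scaling were chosen only after the data were seen. So was the scaling of the fraction arrays to 748 probes, which replaced the percentile over all probes that the design had named and that is kept here as an alternative. The other alternatives were planned. Causes were not tested unless one is named.

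The wild type total RNA response was stable: gcn2 rose by 1.86 to 2.3 and kept its call in all 15 alternatives, and the number of changed genes stayed between 1820 and 2412 when single cultures were left out. It was 1467 with spike-in scaling and 1584 with a minimum of 1.5-fold, which asks for more by construction. Of 2847 values of named genes under alternatives that keep all cultures, 2524 kept direction and side of the threshold, 135 kept direction but fell short of it, 97 came to pass it and 91 changed direction. Of 1488 values with a culture left out, the numbers were 1346, 95, 38 and 9. Of 258 list calls 120 held, 127 fell short and 11 had the other direction, and of 378 with a culture left out 336 held and 42 fell short.

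The index count of 277 in wild type was 4 with quantile normalization, 44 with the median of detected genes, 42 with normexp, 0 with spike-in scaling and 0 with the all-probe percentile, and 299 with the value table of the authors. The all-probe percentile is the scaling first planned. The count was 507 with no filter on dim probes, 2 with genes above background on every array and 129 on all wild type fraction arrays, where fewer genes are tested, and 593 with trend and robust settings. By definition of the index it was 605 as a slope, 816 as fractions 6 and 7 minus 1 and 2, 0 as fractions 5 to 7 minus total RNA, 0 as fractions 4 to 7 minus 1 to 3 and 0 after centring. With a replicate block it was 2, and 2272 in 1 fit over 56 arrays with culture as a random block (consensus correlation 0.478). That fit takes its spread from single fraction arrays, so the fractions of 1 gradient act as replicates. The culture is the replicate, so the count of 2272 cannot be set beside the others. Leaving out single cultures gave 0 (treated replicate 3) to 1431 (untreated replicate 3).

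The count of 153 genes whose total RNA response differs was 597 with spike-in scaling, 84 with no filter on dim probes, 298 with trend and robust settings, and 21 (without untreated replicate 2) to 309 (without treated replicate 1). For untreated gcn2D against wild type in total RNA, the count of 4 was 7 with normexp, 21 with spike-in scaling, 2 on every array and 3 to 40 without single cultures. For the index difference the count of 0 was 1 with no filter, 10 with fractions 6 and 7 minus 1 and 2, and 0 to 3 without single cultures; limma gave 96 genes at an unadjusted p under 0.05. For the untreated index the count of 1 was 100 with quantile normalization, 2486 with the median of detected genes, 2153 with normexp, 1743 with no filter, 2 as a slope and 7 as fractions 6 and 7 minus 1 and 2. It was 0 with spike-in scaling, on every array, on all wild type fraction arrays, as fractions 5 to 7 minus total RNA, as fractions 4 to 7 minus 1 to 3 and as fractions 5 to 7 minus fraction 1, against 194 in limma at an unadjusted p under 0.05, and 1 to 5 without single cultures.

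By fraction, quantile normalization gave 74 genes in fraction 4 and 185 in fraction 6, and the all-probe percentile 71 and 134. A replicate block gave 341, 1284, 648, 228, 667 and 402 in fractions 1, 2, 3, 5, 6 and 7. Without single cultures the counts were 65 to 125, 69 to 348, 97 to 254, 0 to 63, 0 to 150, 111 to 558 and 50 to 269 in fractions 1 to 7.

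With an estimated correlation 0 lists passed in each of the 6 contrasts. With fry 3 passed for the total RNA difference and 0 for untreated total RNA and for the 3 index contrasts. Quantile normalization gave 3, 5 and 2 index lists for wild type, the difference and untreated gcn2D. Without single cultures the index lists were 6 to 11 in wild type and 3 to 8 in untreated gcn2D. fry asks whether a list moves and does not compare it with other genes, which by construction gave the other direction for wild type index lists of arginine (adjusted p = 0.324), branched-chain (0.598), aromatic (0.325), methionine and cysteine (0.227), glutamate to asparagine (0.324), aminoacyl-tRNA synthetases (0.907), cytosolic ribosomal proteins (0.935), heat shock (0.881) and purine synthesis (0.742). For the index difference it did so for cytosolic ribosomal proteins (0.964) and core stress genes (0.812).

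Fractions 5 to 7 minus total RNA shares the total RNA arrays with the other measure, which by construction turns the correlation of total RNA and index responses to -0.45 in wild type and -0.514 in gcn2D. With quantile normalization the gcn2D correlation was 0.27. As a slope, the mean rho with coding span was 0.176 and noncoding RNAs stood at -0.53. The slope is a log2 change per fraction, so that value is not on the scale of the -2.22 of the main index and does not show a smaller difference.

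Single genes changed direction as follows, given as log2 values. With spike-in scaling the total RNA difference of fil1 was 0.15 and its untreated difference -0.5. For the wild type index, spike-in scaling gave car2 0.04, arg12 0.1, arg41 0.19, aro2 0.1 and trp2 0.14, quantile normalization his5 -0.19 and leu1 0.09, normexp arg12 0.18, arg41 0.14 and trp2 0.06, and the all-probe percentile his5 -0.3. Centring gave gcn2 -0.02 and his5 -0.34, the slope arg41 0.01, fractions 6 and 7 minus 1 and 2 arg41 0.08, and fractions 5 to 7 minus fraction 1 trp2 0.13. Fractions 5 to 7 minus total RNA subtracts the total RNA response by construction. It gave hsp3101 -0.59, gnr1 0.5, car2 0.44, arg12 0.61, arg41 0.52, ilv5 0.06, aro1 0.34, aro2 0.4, trp2 0.48, sua1 0.24, hom3 0.44, met10 0.44 and gln1 0.32. It also gave ser3 0.68, gdh1 0.22, frs1 0.1, frs2 0.18, krs1 0.25, rpl22 0.1, rpl3802 0.04, rpl35A01 0.07, sks2 0.16, pyk1 0.05, ura4 0.28 and ade10 0.39.

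The gcn2 probe was above background on no gcn2D array, so its index differences and its untreated index below are of background and their directions have no meaning. For the index difference, spike-in scaling gave gcn2 -0.07 and his5 -0.36, and the median of detected genes gcn2 -0.03 and his5 -0.32. Normexp gave gcn2 -0.01, his5 -0.14, siw14 0.08, urh2 0.1, mrps28 0.03, abc3 0.18, frp1 0.23 and urg1 -0.27. For gcn2 the slope gave -0.01, fractions 6 and 7 minus 1 and 2 gave -0.3 and fractions 5 to 7 minus fraction 1 gave -1.13. Fractions 5 to 7 minus total RNA gave gcn2 -0.08, his5 -0.82, SPNCRNA.1376 -0.47, gnr1 -1.43, frs1 -0.19, frs2 -0.14, hrs1 -0.21, rps2801 -0.31 and rps27 -0.38. It also gave rpl3802 -0.34, plr1 -0.25, hsp78 -0.09, psi1 -0.2, pgi1 -0.3, pdc101 -0.04, ade8 -0.13, ura4 -0.02 and SPNCRNA.134 -1.32.

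For the untreated index, the median of detected genes gave fil1 0.87, rpl101 0.28, rpl1602 0.33 and rpl6 0.39, and spike-in scaling gave fil1 0.04. Normexp gave his5 -0.19, pre1 -0.52, pre4 -0.19, pts1 -0.43, atp17 -0.28 and sdh2 -0.12. Fractions 5 to 7 minus total RNA gave gcn2 2.38, fil1 0.15, pre1 -0.06 and SPNCRNA.1376 0.18. Without single cultures the ranges that crossed 0 were -0.1 to 0.14 for untreated fil1 in total RNA, -0.32 to 0.05 for car2 and -0.11 to 0.16 for arg41 in the wild type index, -0.03 to 0.16 for his5 and -0.05 to 1.54 for urg1 in the index difference, and -0.58 to 0.02 for fil1 in the untreated index.

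The brightest probe per gene was not run, as each gene has 1 probe, nor was a slide block apart from the culture block or an index within 1 slide, as each slide holds 1 culture. Upstream start codons in leaders were not analysed here, as no genome sequence was used. Signal over background limits the fractions most, where as few as 13.26% of probes stood well above background on an array.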

Other observations

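The tests of scaling, untreated replicate 1, dim probes, fraction order and the fil1 difference in this part were chosen only after the result was seen, as was the demand that most of the glucose-repressed genes be above background in both genotypes.

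The gcn2D values are differences of 1 treated culture from 1 untreated culture, with no test, so whether they are a response to 3AT stays open. Chaperone genes that refold proteins after heat had large positive values, with hsp104 at 3.46, hsp78 at 3.4 and ssa1 at 2.74, and the median of the heat shock list was 0.403. Of the 27 lists, the highest medians were those of ribosome biogenesis (0.465), long noncoding RNAs (0.444) and heat shock genes. The lowest were those of nitrogen starvation (-0.676), amino acid transport (-0.423) and histidine synthesis (-0.379). With spike-in scaling these last were 0.00773, 0.261 and 0.305. Relative to all genes, normexp took nitrogen starvation from -0.655 to -0.228 and transport from -0.402 to -0.214, so the order is that of the main processing.

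In wild type the gradient position of aminoacyl-tRNA synthetase genes, which charge tRNAs, was 0.651 ± 0.0921 before and 0.146 ± 0.0738 after 3AT relative to the median coding gene (SD, n = 3), and in gcn2D it stood at 0.8 and 0.793. Purine and pyrimidine synthesis genes stood at 0.886 ± 0.183 before and 0.166 ± 0.0881 after 3AT in wild type, and glycolysis genes at 1.32 ± 0.604 and 0.716 ± 0.149. The size of these shifts depends on the processing, here on background correction with normexp or on quantile normalization. Relative to all genes, the wild type change of aminoacyl-tRNA synthetases went from -0.488 to -0.0846 with normexp and their genotype difference from 0.619 to 0.0336. The wild type change of purine synthesis went from -0.421 to -0.132 with normexp, and that of glycolysis from -0.573 to -0.0607 with quantile normalization.

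The higher polysome index of 271 genes in wild type after 3AT was weighed against technical explanations. Scaling of the fraction arrays stays a candidate explanation. With the percentile taken over all probes, 0 genes passed the threshold with a higher index. The median response of all genes went from 0.518 (SE 0.228) to 0.0385 (SE 0.0293). That percentile moves all genes of a culture alike and nearly centres them. The loss of higher genes was thus close to fixed in advance and cannot decide the cause. The gradient of untreated wild type replicate 1 stays open, as the median response without it was 0.321 (SE 0.153) against 0.518 with it. Dim probes near background also stay open, with a median of 0.347 (SE 0.173) over genes above background on all 42 wild type fraction arrays. Treatment with 3AT is the biological difference the design names, and these tests do not separate it from the scaling.

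The higher levels of inv1, agl1 and ght4 in the untreated gcn2D culture were weighed as well. Less glucose in that culture stays open: 6 other glucose-repressed genes had a fitted median difference of 1.37, but only gld1 (3.41) and dak1 (0.39) were above background in both genotypes. The probes of fbp1, ght3, ght6 and dak2 were above it on 0 of 3 untreated wild type arrays, so their values have no exact size, and with each at the smallest change the background allows and ght6 left out the median of 5 genes was 1.06. A slide effect cannot be told apart, because 1 culture, this one, was on its slide. Loss of Gcn2 is the untested biological explanation.

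Whether high fraction numbers hold more ribosomes per mRNA stays open. Noncoding RNAs stood low in the index, but longer coding spans did not stand clearly higher: Spearman's rho of index and span ran from -0.0605 to 0.113 over the 8 cultures, and in untreated wild type the fifth of genes with the longest spans stood at 0.0237 ± 0.11 (SD, n = 3) from the median coding gene.

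That the rise of the fil1 index needs Gcn2 was tested by the difference in response, -1.04 ± 0.639, with an unadjusted limma p of 0.117, which leaves the hypothesis open. In fraction 3 the fil1 probe was not above background in either gcn2D culture.

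The 6 wild type cultures can be split in 10 ways, too few for a share under 0.05. Every wrong split has treated and untreated cultures in both groups. It keeps part of the treatment difference and adds the rest to the spread, so its counts do not stand for chance alone. For total RNA the real split gave 2514 genes and the highest other split 0, and 1 of the 10 gave as many as the real one. For the index the real split gave 277 and the highest other 0, again 1 of 10. In fractions 1 to 7 the real counts were 146, 186, 179, 39, 109, 295 and 177, and the highest other was 0 in each, 1 of 10. For gene lists the real count was 13 in total RNA and the highest other 17, with 3 of 10 as large, and 10 for the index and the highest other 11, with 2 of 10 as large.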
